A study of Bos taurus with 12 samples.

How the data were processed

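The study measured RNA levels in the filamentous extra-embryonic membrane of bovine embryos, the tissue outside the embryonic disc, on day 15 after insemination. Embryos were made by in vitro fertilisation and cultured with either 10 ng/ml recombinant bovine CSF2 (colony-stimulating factor 2, a cytokine also called GM-CSF) or its vehicle from day 5 to day 7. They were then transferred to recipients on day 7 and flushed on day 15, and their sex was found by PCR, per the labels. The 12 samples fall into 4 groups: 2 control males, 4 CSF2 males, 3 control females and 3 CSF2 females. The labels give each sample a replicate number but do not say whether a sample is a single embryo, so p-values measure the spread between these samples.

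Amplified RNA was labelled chemically with Cy3 or Cy5, and a pair of samples was hybridised to each of 6 Agilent arrays of the EmbryoGene design on 2 slides, per the labels. Each sample is therefore one channel of an array. Every array held a single sex. Of the 3 male arrays, 2 paired a control in Cy3 with a CSF2 sample in Cy5, and the remaining one held CSF2 samples in both channels. All 3 female arrays paired a control with a CSF2 sample, which was in Cy3 on 2 arrays and in Cy5 on 1. Slide 1 carried all male samples and 1 female array, and slide 2 carried the other 2 female arrays.

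Spot intensities are linear mean and median pixel values that were neither background corrected nor normalised, per the file headers. The files used here give no local background per spot and do not explain their spot marks of 2 and 3. The authors deposited a second table of values on a log2 scale, whose median was 7.98 in every column. Each of its columns ranked with the mean intensity of its own channel at a rank correlation of 0.993 to 0.997, and with any other channel at 0.936 or less. The normalisation behind the deposited log2 values is not given in the sources used here, and they served only as an alternative.

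Mean intensities were corrected with the normexp method at an offset of 50, on the foreground only, because no local background was given. They were then normalised within arrays by loess, with control spots at weight 0, and between arrays by the Aquantile method, in limma 3.58.1 under R 4.3.3. Marked spots, 714 to 793 of the 43794 probes per sample, were left out. A probe counted as above background in a sample when its mean intensity exceeded the mean plus 2 SD of the 153 negative control spots of that channel. Between 25128 and 31709 probes per sample passed, and 35961 probes passed in at least 2 samples. Of these, 35693 had enough unmarked spots to be fitted.

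All 12 samples entered one separate-channel model in limma with the 4 groups and the dye as terms. The 2 samples of an array were allowed to correlate, with 0.26 estimated as the correlation. The coefficients equal those of the limma function for such designs where no spot was marked, and were computed exactly for each pattern of marked spots elsewhere. Moderated tests were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. The number of arrays limits the precision: the median standard error of a log2 difference was 0.16 for CSF2 in females and 0.21 in males.

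The procedure was tested on simulated data with the levels, spread and array correlation of the 35693 probes, drawn independently of each other. For the male CSF2 comparison, 43.3% of probes with a log2 change of 1 were recovered, 86.6% at a change of 2 and 98.5% at 4. For the female CSF2 comparison the shares were 64.2%, 89.6% and 98.5%, and for the control sex difference 34.3%, 85.1% and 98.5%. False calls in the fit of 12 samples numbered 11 for the male CSF2 comparison, 13 for the female one and 5 for the control sex difference, or 6.7%, 7.2% and 3.3% of all calls. In the fit of the 6 female samples alone, 26 false calls stood beside 171 recovered probes, or 13.2% of its calls. The adjustment aims at a false share of 0.05. These shares come from a single draw of noise used for all comparisons, so how far they vary was not measured. With no change simulated, 10 draws gave 0 calls for the female CSF2 comparison in the fit of 12 samples. A fit of the 6 female samples alone estimated an array correlation of 0.46 to 0.49 in the same draws, although 0.26 was simulated, and gave between 0 and 1 calls.

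Probes are identified by array design numbers. Of the 43794 probes, 0 carried a gene name in the files, and 0 entries of the reference gene table used here matched a probe. The 24 gene lists, the check of sex labels by named genes, the choice of one probe per gene and its alternative, the mean of a gene's probes, all needed gene names and were not run. The fixed rule for named genes was replaced by this one: for each comparison, the 2 probes in each direction with the smallest unadjusted p. Where a probe was above background in no sample of a group, its fold is given as a lower bound, from the higher of the lowest detected level and the probe's own level in each sample of that group. Such bounds hold for the main processing, and some alternatives gave smaller differences. They are also open to dye bias, since dyes were not balanced.

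The comparisons, their model and most alternatives were fixed before the data were examined. The alternatives covered background correction, normalisation, the deposited values, the dye term, the filter on dim probes, the treatment of arrays, slides and replicate numbers, subsets of arrays, the variance model and leaving out each sample in turn. Alternatives that kept marked spots, used median intensities, exchanged the array correlation, averaged the sex difference over treatments or varied the fit within one sex were chosen after seeing the data.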

Results

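RNA levels were compared between CSF2-treated and control membranes within each sex, and between the sexes within each treatment. Between 57.4% and 72.4% of the 43794 probes were above background per sample. Correlations between samples ranged from 0.926 to 0.976 across probes. The median SD between samples was 0.19 on the log2 scale in control and in CSF2 females, 0.17 in control males and 0.24 in CSF2 males. These SDs come from 3, 3, 2 and 4 samples. Median SDs of few samples run low, and the control males were all in Cy3, so the values do not rank the groups. Replicate spots of positive controls within a channel had a median SD of 0.19. That SD was taken on log2 intensities before correction and normalisation, so it cannot be set against the SD between samples.

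The first comparison asked how the membranes of males exposed to CSF2 differed from those of control males on day 15. No probe passed the threshold in limma among 35600 tested, and 1439 had an unadjusted p under 0.05, against 1780 expected by chance. The latter count was 2408 without CSF2 replicate 2 and 2420 without the array that held CSF2 males in both channels. It was 2350 in a fit of the 6 male samples. CSF2 replicate 2, on that array, was the only CSF2 male in Cy3. Without it, CSF2 and dye coincided among the males, and only the female arrays informed the dye term. The probes nearest to the threshold were EMBV3_16582 and EMBV3_34036 on the higher side. EMBV3_34036 measured 9.62 ± 0.09 (SD, n = 4) on the log2 scale in CSF2 males and 8.57 ± 0.04 (SD, n = 2) in controls, a fitted log2 difference of 1.15 with a standard error of 0.18 (limma adjusted p = 1). EMBV3_16582 was above background in all 4 CSF2 males and in neither control, with means of 7.59 ± 0.09 (SD, n = 4) and 6.59 ± 0.02 (SD, n = 2), at least 1.31-fold higher (limma adjusted p = 0.877). Its fitted log2 difference was 1.01, but 0.57 with no background correction and 0.64 with the deposited values or median intensities.

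On the lower side, EMBV3_20623 had a fitted log2 difference of -3.23 with a standard error of 0.52. It measured 11.02 ± 0.81 (SD, n = 2) in the CSF2 males with an unmarked spot and 13.63 ± 0.88 (SD, n = 2) in controls (limma adjusted p = 1). With marked spots kept, all 4 CSF2 males entered and the difference was -1.77. The marked spots had mean intensities of 14916 in Cy3 and 2936 in Cy5. Both controls, in Cy3, had 9669 and 21622, and the CSF2 males that entered, in Cy5, had 1217 and 2800. Dye and CSF2 thus coincided among its unmarked male spots. EMBV3_18346 was above background in both controls, at 7.5 ± 0.13 (SD, n = 2), and in 0 of 4 CSF2 males, at 6.83 ± 0.12 (SD, n = 4), a level at least 1.26-fold lower (limma adjusted p = 1). The fitted log2 difference of EMBV3_18346 was -0.68, but -0.38 with no background correction and -0.31 with median intensities. Both male controls were labelled with Cy3. Without a dye term the 4 differences kept their sign, at 1.04 for EMBV3_34036, 0.99 for EMBV3_16582, -2.61 for EMBV3_20623 and -0.65 for EMBV3_18346. With 3 of 4 CSF2 males in Cy5, that fit takes dye bias into the CSF2 difference, so the kept sign does not address dye. Without the array that held CSF2 males in both channels, 2 probes passed, in a fit where CSF2 and dye coincided among the males.

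In females, CSF2 and control membranes were compared on 3 arrays that each held one of both. No probe passed the threshold in limma among 35628 tested in the fit of all 12 samples. An unadjusted p under 0.05 was reached by 2954 probes, 1212 of them higher and 1742 lower with CSF2, against 1781 expected by chance. That count moved when single samples were left out. It was 1684 without CSF2 female replicate 2, 1828 without control female replicate 1 and 4479 without CSF2 male replicate 2. CSF2 female replicate 2 was on the only female array with CSF2 in Cy5, so leaving it out also weakens the separation of CSF2 from dye. The count was 1744 with samples treated as independent. EMBV3_18114 measured 7.59 ± 0.14 (SD, n = 3) with CSF2 and 8.33 ± 0.06 (SD, n = 3) in controls, a fitted log2 difference of -0.76 with a standard error of 0.1 (limma adjusted p = 0.447). EMBV3_40349 measured 9.55 ± 0.25 (SD, n = 3) with CSF2 and 10.72 ± 0.07 (SD, n = 3) in controls, a difference of -1.18 with a standard error of 0.16 (limma adjusted p = 0.447). Both were lower with CSF2 on all 3 female arrays. On the higher side, EMBV3_03487 differed by 0.75 with a standard error of 0.14 and EMBV3_01652 by 1.03 with a standard error of 0.19 (limma adjusted p = 0.447 for each). Both were higher with CSF2 on all 3 female arrays, by 0.33, 1.11 and 0.33 for EMBV3_03487 and by 0.61, 1.78 and 0.2 for EMBV3_01652.

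The female count depended on which samples shared the model. A fit of the 6 female samples alone called 1483 probes, 534 higher and 949 lower with CSF2, with an estimated array correlation of 0.55. With the correlation of 0.26 from the 12-sample fit it called 0, with the array as a fixed block 74, and without either CSF2 replicate 1 or CSF2 replicate 2 it called 0. Without control replicate 2 it called 1. All 534 and 949 probes kept their direction in the 12-sample fit, which holds the same female samples. Of them, 350 and 623 had an unadjusted p under 0.05 there. In the fit of the 6 female samples, 7683 probes had an unadjusted p under 0.05. Leaving out CSF2 replicate 1 gave 7086, CSF2 replicate 2 gave 2029 and control replicate 2 gave 2259. The last 2 shared the only female array with CSF2 in Cy5, which helps to separate CSF2 from dye.

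**Figure D1:**
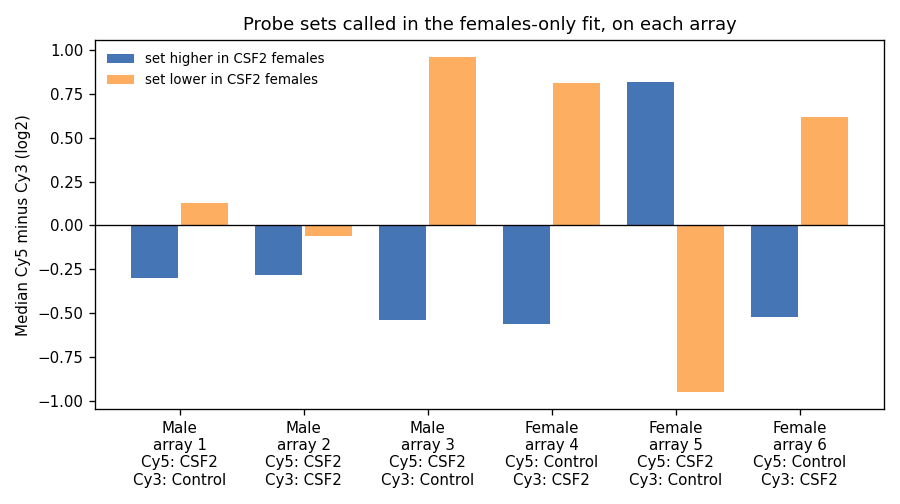
Median Cy5 minus Cy3 difference (log2) on each array of the 534 probes higher and the 949 probes lower with CSF2 in the fit of the 6 female samples; bars are medians over probes. Array 5, the only female array with CSF2 in Cy5, has 0.82 for the higher set, and the other arrays have between -0.56 and -0.28. The male arrays also had CSF2 in Cy5. The sets were chosen on the female arrays.

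**Figure D2:**
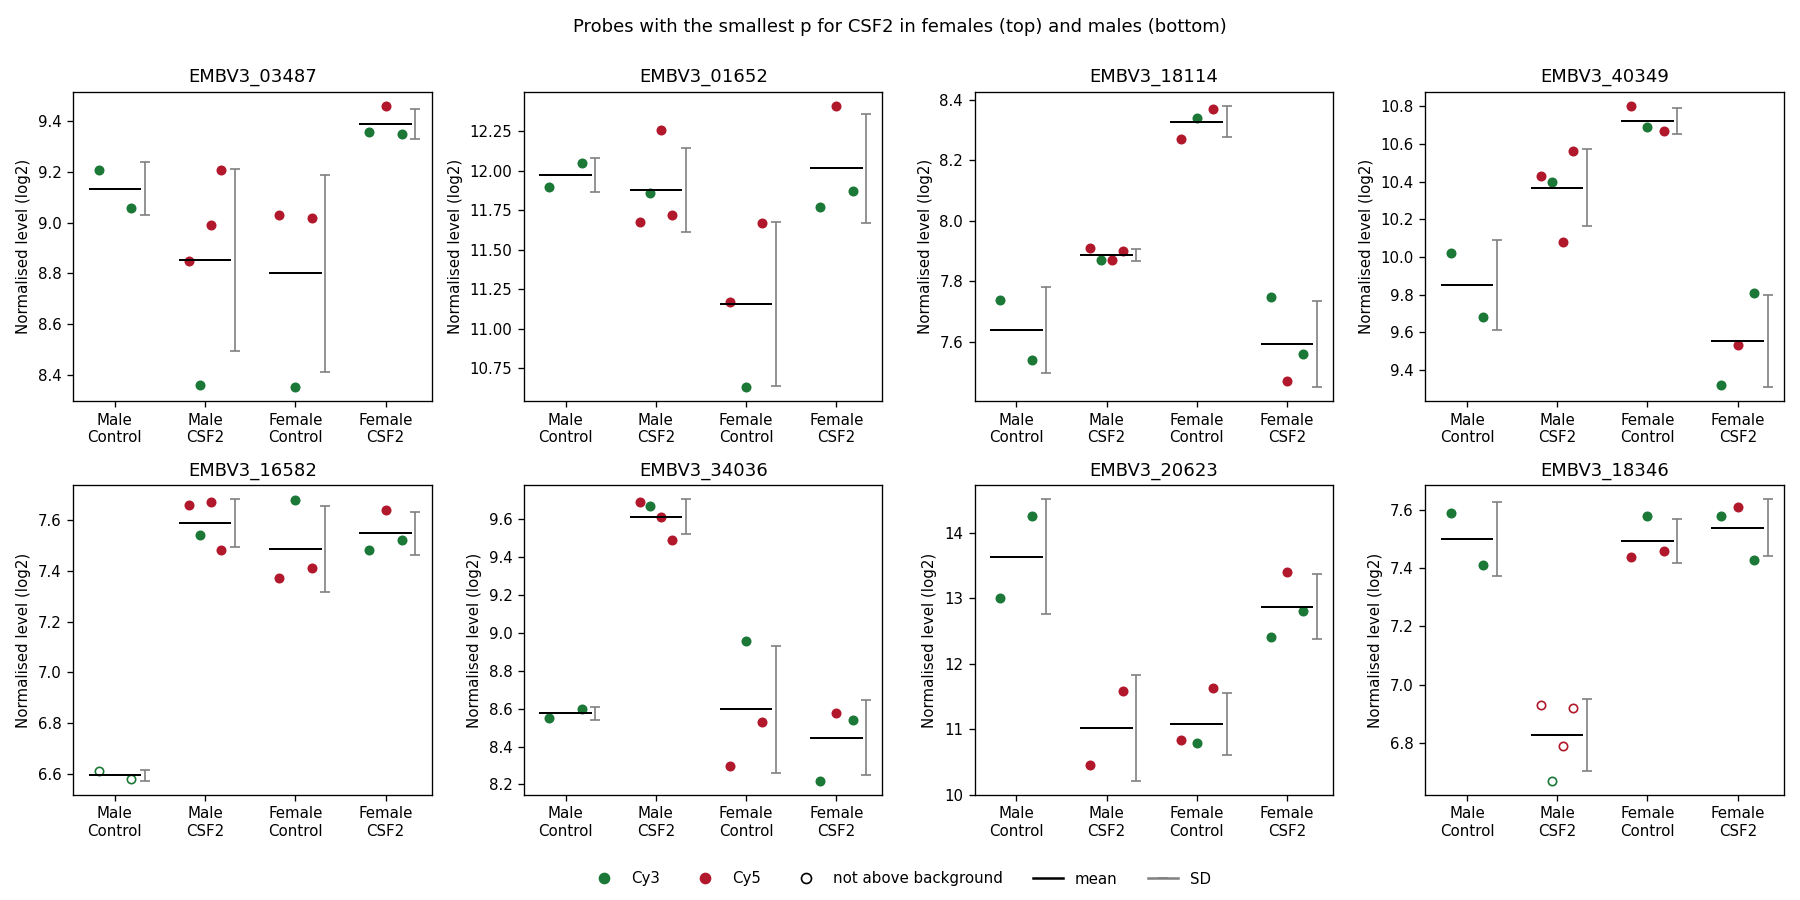
Normalised log2 levels of the probes with the smallest p for CSF2 in females (top) and in males (bottom); points are samples coloured by dye, open points were not above background, horizontal lines are group means and grey bars are SD. EMBV3_18114 had a mean of 7.59 in CSF2 females and 8.33 in control females, and EMBV3_34036 had a mean of 9.62 in CSF2 males and 8.57 in control males.

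The series names an interaction of CSF2 with sex, which was tested as the CSF2 effect in females minus that in males. No probe passed the threshold in limma among 35569 tested, and 2859 had an unadjusted p under 0.05, against 1778 expected by chance. The latter count was 4363 without CSF2 male replicate 2 and 4570 without the array that held CSF2 males in both channels. Both removals left CSF2 and dye coinciding among the males. The count was 1864 with samples treated as independent. The widest named difference was that of EMBV3_20623, at 5.22 on the log2 scale with a standard error of 0.68 (limma adjusted p = 0.436). Its CSF2 minus control differences were 1.58, 2.61 and 1.16 on the female arrays and -2.56 and -2.66 on the male arrays. EMBV3_02512 had an interaction of 1.67 with a standard error of 0.28, EMBV3_01267 one of -1.79 with 0.25, and EMBV3_40349 one of -1.77 with 0.28 (limma adjusted p = 0.436 for each). EMBV3_01267 was lower with CSF2 on the female arrays, by -0.98, -0.8 and -0.88, and higher on the male arrays, by 1.36 and 0.82. With marked spots kept, the interaction of EMBV3_20623 was 3.43. Its unmarked male spots had controls in Cy3 and CSF2 samples in Cy5 only, so its male differences cannot be told from dye within males. Without the array that held CSF2 males in both channels, 1 probe passed, again with CSF2 and dye coinciding among the males.

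Control females were compared with control males to describe the sex difference without CSF2. Of 35569 probes tested, 2 passed the threshold in limma, both lower in females, while 2186 had an unadjusted p under 0.05 against 1778 expected by chance. EMBV3_39949 measured 12.86 ± 0.11 (SD, n = 2) in control males and 6.94 ± 0.12 (SD, n = 3) in control females, where it was above background in 0 of 3. It was at least 52.9-fold lower in females (limma adjusted p = 5.23e-05). That bound, 5.72 on the log2 scale, depends on the processing. The fitted difference was -5.04 with no background correction and -5.08 with the deposited values. EMBV3_29688 measured 9.16 ± 0.13 (SD, n = 2) in control males and 6.79 ± 0.24 (SD, n = 3) in control females, again with 0 of 3 above background, and was at least 4.07-fold lower (limma adjusted p = 0.0204).

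On the side higher in females, EMBV3_01267 differed by 1.31 with a standard error of 0.19 and EMBV3_09055 by 1.23 with a standard error of 0.19 (limma adjusted p = 0.582 for each). EMBV3_29688 had a fitted log2 difference of -2.42 and passed in 12 of the 26 alternatives that tested it. Its call was lost with the slide as a block, at -2.33 (limma adjusted p = 0.391), and with a replicate block, at -2.41 (limma adjusted p = 0.126). The deposited values, at -1.83 (limma adjusted p = 0.553), and no background correction, at -1.69 (limma adjusted p = 0.0771), lost it too. It was also lost without control male replicate 1, at -2.58 (limma adjusted p = 0.121), or 2, at -2.25 (limma adjusted p = 0.177). On slide 1 alone, which holds 1 control female, 0 probes passed and EMBV3_29688 differed by -2.15 (limma adjusted p = 0.906). EMBV3_39949 could not be tested there, because its marked spots left the dye and the groups inseparable. With the slide as a block EMBV3_39949 differed by -5.88 (limma adjusted p = 0.002).

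Among CSF2-treated membranes the same 2 probes passed in limma, of 35617 tested, and 2178 had an unadjusted p under 0.05 against 1781 expected by chance. With the slide as a block that count was 1032. EMBV3_39949 measured 12.44 ± 0.28 (SD, n = 2) in the CSF2 males with an unmarked spot and 7.02 ± 0.09 (SD, n = 3) in CSF2 females, at least 37.2-fold lower in females (limma adjusted p = 8.11e-05). In the other 2 CSF2 males its spot was marked, with mean intensities of 8226 and 5706, beside 5584 and 4279 in the males that entered. EMBV3_29688 measured 9.4 ± 0.25 (SD, n = 4) in CSF2 males and 6.86 ± 0.11 (SD, n = 3) in CSF2 females, at least 4.51-fold lower (limma adjusted p = 0.0023). On the higher side, EMBV3_02512 differed by 0.99 with a standard error of 0.18, and EMBV3_18346, above background in 3 of 3 CSF2 females and 0 of 4 CSF2 males, was at least 1.3-fold higher in females (limma adjusted p = 0.788 for each). The fitted log2 difference of EMBV3_29688 was -2.51. Its call was lost with the slide as a block, at -2.43 (limma adjusted p = 0.0838), and without CSF2 female replicate 2, at -2.51 (limma adjusted p = 0.189). Slide 1 alone, with 1 CSF2 female, gave 0 calls, with EMBV3_29688 at -2.56 (limma adjusted p = 0.745) and EMBV3_39949 again not testable. Without the male array with CSF2 in both channels, 3 probes passed, all lower in females, of which 1 was among the 2 called here; EMBV3_29688 was then at -2.39 (limma adjusted p = 0.107).

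**Figure D3:**
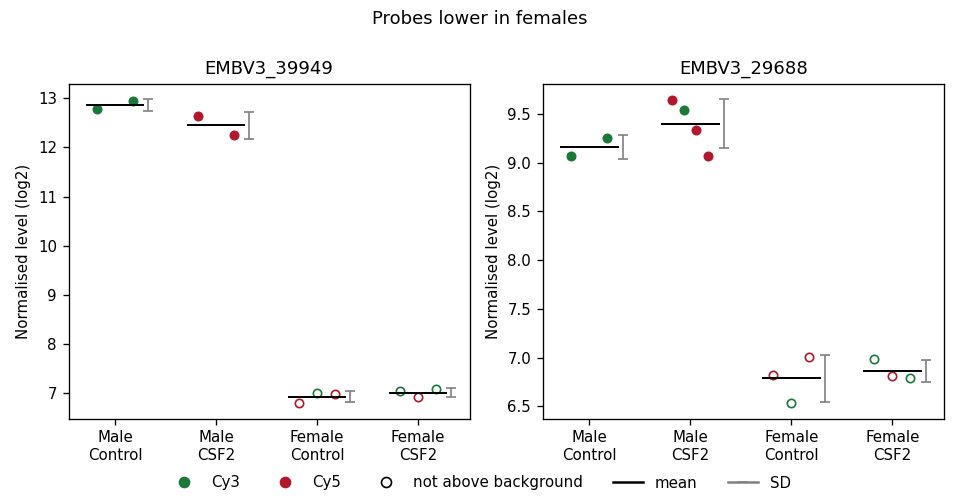
Normalised log2 levels of both probes that passed the threshold between the sexes, by group; points are samples coloured by dye, open points were not above background, horizontal lines are group means and grey bars are SD. EMBV3_39949 had means of 12.86 in control males and 6.94 in control females, and all female points of both probes are open.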

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

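The tests on the probes called in females alone, on dye, on variation between embryos, on residual spreads and on the array correlation were chosen after the data had been seen. What the residual spreads and the exchange in females alone would show was written down before those values were seen, when the count with independent samples was already known.

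The probes that the fit of the 6 female samples called had medians of opposite sign on the female and male arrays, a difference that was not tested. Over the 534 probes higher with CSF2 in females, the median CSF2 minus control difference was 0.56, 0.82 and 0.52 on the female arrays and -0.3 and -0.54 on the male arrays. Over the 949 probes lower with CSF2, it was -0.81, -0.95 and -0.62 on the female arrays and 0.13 and 0.96 on the male arrays. The female values are of probes chosen for that direction.

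Gene-specific dye bias may contribute to the male direction, because CSF2 was in Cy5 on both male arrays that held a control. On the male array with CSF2 in both channels, Cy5 minus Cy3 was -0.28 over the higher set, close to the -0.3 of one of the other male arrays, and -0.06 over the lower set, where the others had 0.13 and 0.96. A single array with unlike answers from the sets leaves this open. The same question bears on the female calls, since CSF2 was in Cy3 on 2 of the 3 female arrays. Without a dye term, the fit of the 6 female samples called 0 probes, but its estimated array correlation also fell, from 0.55 to 0.13. With the dye term kept, a correlation of 0.26 gave 0 calls as well, so this 0 cannot be laid to dye. Over the higher set, Cy5 minus Cy3 was -0.56 and -0.52 on those 2 arrays and 0.82 on array 5, with CSF2 in Cy5. Over the lower set it was 0.81, 0.62 and -0.95. The sets were chosen on these same arrays, so the values do not settle it. In the fit of the 6 male samples with a dye term, the median male effect was 0.06 over the higher set and 0.16 over the lower set, so the opposite direction of the higher set was not kept. In that fit 45.5% of the higher set was lower and 62.8% of the lower set was higher in CSF2 males. Across 34783 probes, which are not independent replicates, the effects fitted apart in each sex had a Pearson r of -0.04 and a Spearman rho of -0.03. Variation between embryos that is unrelated to CSF2 could also give the pattern. A score, the mean of the higher set minus that of the lower set, ranged over 1.34 among the 4 CSF2 males, from -0.73 to 0.61, beside a CSF2 difference of 1.56 in females. The 0.61 came from the only CSF2 male in Cy3, so that range may hold dye bias too. The 2 control males, both in Cy3, scored -0.37 and 0.96. The female difference is one of means over probes chosen for it, so it is not a like measure. Spreads of this size leave this explanation open as well. A response to CSF2 that differs with sex stays open and was not tested beyond the interaction, which called 0 probes in limma. There, 2859 probes had an unadjusted p under 0.05, with 1864 for independent samples and 4363 without CSF2 male replicate 2. Without that replicate, CSF2 and dye coincided among the males.

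Why the fit of the 6 female samples called 1483 probes, and the fit of 12 samples 0, was left open in part. Exchanging the array correlation estimated from 3 arrays, 0.55, for the 0.26 of the 12 samples left 0 calls in females alone. The array as a fixed block, which uses no estimated correlation, called 74, of which 54 were among the 1483 in the same direction. So the count needed that estimate. The 74 calls did not use it, but 6 samples with terms for group, dye and array leave little to estimate each probe's spread. Those calls therefore lean on the spread that the moderated tests borrow across probes. The reverse exchange, 0.55 in the fit of 12 samples, also gave 0 calls, with 4716 probes at an unadjusted p under 0.05, so the array correlation alone did not produce the 1483. The simulated draws with a correlation of 0.26 gave estimates of 0.46 to 0.49 in females alone, but between 0 and 1 calls. With changes simulated, in a single draw, 13.2% of the calls in females alone were false. Unadjusted p under 0.05 was reached by 7683 probes in females alone and by 5213 after the exchange. By chance 1760 would be expected, and the draws with no change simulated gave 2742 to 3083. The draws took probes as independent, so they understate how far such counts vary among probes that correlate. Other splits of the 6 female samples gave 998 to 4180, but most part fewer arrays than the real one and so have another precision. The 2 of like form gave at most 2218. In females alone the count for the real split was 2029 without CSF2 replicate 2 and 2259 without control replicate 2. It was 6840 to 8081 when any other female sample was left out. CSF2 replicate 2 and control replicate 2 shared array 5, the only female array with CSF2 in Cy5. Without either, CSF2 and dye are harder to separate, so the fall need not reflect those samples' values alone. The median residual SD of the male fit was 1.17 times that of the female fit, which fell between the bounds set beforehand and leaves open whether a larger male spread could account for the difference.

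The positive control spots called E1A, 10 probes with 32 spots each per array, took no part in the comparisons. Their median signal lay 4.31 to 6.25 log2 units above that of the negative controls, a signal in data outside the measured probes. It split by dye, at 4.31 to 4.68 in Cy3 and 5.81 to 6.25 in Cy5.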

How the results depend on the processing

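Alternatives that kept marked spots, used median intensities, exchanged the array correlation or varied the fit of one sex were chosen after seeing the data. Without the male array with CSF2 in both channels, the male CSF2 count was 2 and the interaction count 1. CSF2 and dye then coincided among the males. Both counts were 0 under every other alternative run. The female CSF2 count was 1483 with only the samples of that sex and 0 under the others. The control sex count of 2 became 1 with no background correction, the authors' deposited values, the slide as a block, the replicate block or without the male array with CSF2 in both channels, 3 with no dye term (1 higher in females and the same 2 lower), and 0 on slide 1 alone or with probes above background in all 12 samples, which removes both called probes. Leaving out each sample gave between 1 and 2 calls, with 1 without either control male, CSF2 male replicate 3, control female replicate 1 or 2, or any CSF2 female. The CSF2 sex count of 2 became 1 with the deposited values or the slide as a block, 3 without the male array with CSF2 in both channels (all lower, 1 shared with the 2) and 0 on slide 1 alone or with probes above background in all 12 samples, and leaving out each sample gave between 1 and 2, with 1 without CSF2 female replicate 2. EMBV3_39949 passed in all 25 alternatives that tested it in each sex comparison, with differences from -6.35 to -5.04 in controls and from -5.83 to -4.67 with CSF2. It was not testable on slide 1. EMBV3_29688 passed in 12 of 26 and 21 of 26, with differences from -2.58 to -1.69 and from -2.64 to -1.83. All named probes kept their sign in every alternative that tested them. They were chosen by p in the same data, which favours a kept sign.

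Within the fit of the 6 female samples, the count of 1483 became 3320 with loess only, 556 with the deposited values, 689 with the slide as a block (at the correlation of 0.55, since none could be estimated), 74 with the replicate block, which is the array in females, and 0 with no dye term, independent samples or the array correlation of the 12 samples. Leaving out each sample, at the correlation of 0.55, gave between 0 and 1681, with 0 without CSF2 replicate 1 or 2, 1 without control replicate 2 and 187 without control replicate 1. The fit with no dye term estimated a correlation of 0.13, so its 0 does not isolate the dye term. The causes were not tested beyond the exchange of the correlation.

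In females the replicate number coincides with the shared array, which the array correlation allows for; in males only number 1 does. Same-numbered females had deviations from their group means correlated at 0.3, -0.09 and 0.27. Same-numbered males had 0.46 and 0.29, so not every correlation was over 0.1. The deviations of the 2 control males mirror each other, so the male values are not separate. Most of these pairs also shared an array, so the values do not show whether replicate numbers mark pairs. The replicate block took the control sex count from 2 to 1 and left the other counts of calls in the fit of 12 samples unchanged. In females alone it called 74, beside 1483. Leaving out a control male leaves 1, assumed to vary like the other groups. The mean of a gene's probes was not run. Signal over background limits the sex probes, whose female levels are bounds.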

Other observations

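The splits between the sexes were written down before their counts of calls were seen, those of whole arrays after the counts of the other splits were known. The averaged comparison, the counts of separated probes by whole arrays and the splits of the female samples were tests chosen after results had been seen.

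Averaged over both treatments, 2 probes differed between the sexes in limma, and both were those named above. EMBV3_39949, measured in 6 females and 4 males, was lower in females by -5.68 on the log2 scale (limma adjusted p = 3.85e-06) and, over 6 and 6, EMBV3_29688 by -2.47 (limma adjusted p = 0.000356), while 1912 probes had an unadjusted p under 0.05 against 1781 expected. Both separated every measured male from every female. Among 33923 probes measured in all 12 samples, 101 had every female above every male and 63 every male above every female, 164 in all. The 37 per direction that 12 independent samples would give is too low a reference, because arrays held a single sex and their samples correlate. The other 9 splits that keep arrays whole separated 54 to 291 probes, with a median of 108, and the 291 came from arrays 1, 2 and 4 against the rest, which mixes the sexes. The count of separated probes therefore does not set the sexes apart. By at least 1 log2 unit, 1 probe had all males above all females and 0 the reverse. A total of 19 probes were above background in all 6 males and in no female, and 11 in all 6 females and in no male. Marked spots counted as not above background, so EMBV3_39949, marked in 2 males, is not among the 19. The counts were not taken for the other splits of arrays, so they have no reference. Without gene names, whether any of these probes lies on a sex chromosome was not analysed here.

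The counts of calls between the sexes do not exclude chance by themselves. Of 462 splits of the 12 samples into 6 and 6, 454 could be fitted and 100 were used. In 6 of these 100, the real one included, the averaged comparison called at least as many probes as the real 2, and the highest other split called 5. Of the 35 splits of the 7 CSF2 samples, 2 called at least 2 probes, the real one included, and the highest other called 2. The real split of the 12 samples keeps both samples of every array together, as only 3 of the 100 did, itself included. The rest of the 100 part arrays and so have another precision, and splits of the CSF2 samples also part arrays. Among the 10 splits that keep arrays whole, too few for a share under 0.05, the real one called 2 and the highest other 1, so 1 split reached that count.

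For CSF2 in females the 10 splits of the 6 samples are too few for a share under 0.05. In females alone the real split called 1483 probes and the highest other 0, so 1 split reached that count. These fits are of unlike form: the real split parts all 3 arrays, and of the 9 others 6 part 1 array and 3 part all 3, of which 1 was fitted without a dye term. The 2 of like form called 0, with at most 2218 probes at an unadjusted p under 0.05, beside 7683 in the real split and at most 4180 in any other. In the fit of 12 samples the real split called 0 and the highest other 1. A count of 0 is reached by all 10 splits whatever the data, so this says nothing about chance. There, 2954 probes had an unadjusted p under 0.05 in the real split, 3368 when CSF2 replicate 1 and control replicates 1 and 2 were set against the rest, and 3009 when CSF2 replicates 1 and 3 and control replicate 2 were. The last of these places all Cy3 females against all Cy5 females.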
